A study of Mus musculus with 6 samples.

How the data were processed

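RNA from mouse samples labelled as chondrocytes, the cells of cartilage, was sequenced in 6 libraries, 3 labelled control and 3 labelled Eldr cKI, with groups and replicate numbers taken from the labels. Per the labels' protocols, total RNA was extracted with Trizol, messenger RNA was enriched by poly(A) selection or ribosomal RNA removal, and libraries were made with a stranded kit and read on an Illumina HiSeq instrument. Which enrichment each library had is not given in the sources used here. Per the submitters' processing notes, the tools were cutadapt, HISAT2 2.0.5 and StringTie, with no parameters. The same notes name the human build hg19, whereas the gene identifiers and loci of the deposited table are those of the mouse. Of 11955 rows, 11017 have exactly the span that the GENCODE M21 annotation of GRCm38 gives their identifier, so coordinates below are those of the table, on that build unless a doubt is stated. Whether strand was used in counting, and how reads with several alignments were treated, is not given in the sources used here.

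Per the file headers, the authors deposited FPKM (fragments per kilobase, scaled to each library's mapped fragments) for each of the 6 libraries. The number of other columns of per-sample values, which would not have been used, was 0. Every row was typed as protein-coding and had a mean FPKM of at least 0.25 over the 6 libraries, as computed from the values. Per the file headers, the authors also deposited a group value called FPKM, a log2 fold change, a linear fold change (a ratio), a p-value and a q-value per row. The group values in the authors' deposited table equal means of log2(FPKM + 1). The deposited log2 fold change is their difference, Eldr cKI minus control, and the deposited fold is 2 to that power. The p-values in the authors' deposited table equal those of an equal-variance two-sample test on log2(FPKM + 1), to within 4.56e-13.

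Fold changes below come from limma 3.58.1 in R 4.3.3, fitted to log2(FPKM + 1) over all 6 libraries with group as the only term. Of the rows, 10772 had a mean FPKM of at least 0.5 and entered the fit. Moderated tests used a mean-variance trend, and the threshold was a Benjamini-Hochberg adjusted p of 0.05. Because of the pseudocount of 1, fold changes of genes at low FPKM are understated. The values held no whole counts, so the count-based tests listed as conditional alternatives were not run. Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, with adjustment over the 31 of 33 lists that had at least 5 genes in the fit. The osteoblast and adipocyte lists fell short of that number and are given only as summed FPKM. Camera with an estimated correlation and fry, which tests whether a list's genes move one way on balance, were alternatives. Single values per library were compared by two-sided exact permutation tests, whose smallest possible p with 3 against 3 is 0.1. Summaries and figures used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

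The design, the alternatives, the lists and the rule for named genes were fixed before the data were examined. The rule took 20 genes whatever their result, among them Eldr, Cdkn2a, Ihh, Mmp13, Col2a1 and Sox9. It added up to 12 rises and 12 falls past the threshold with a mean FPKM of at least 5 in the higher group, no predicted or clone name and no overlap between groups. Where fewer than 5 in a direction qualified, the smallest unadjusted p among genes without predicted or clone names made up 5. It also took 4 members of each list past the threshold, and up to 2 members past the threshold of each other list, of which there were none. Lists of photoreceptor, hepatocyte, cardiomyocyte, receptor and housekeeping genes were written after the values had been seen. Genes named from these lists, the globins, mt-Atp6 and the predicted genes fall outside the rule and were likewise chosen after their values were seen.

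Depth was read from the low FPKM values. In genes with 1 annotated transcript, FPKM times transcript length clustered at a step, taken as the worth of 1 fragment, with a tolerance of 1 percent. Between 32.5% and 53.8% of low values lay within 0.05 of a whole number of steps, so counts could not be recovered and the depths are rough. The fit was tested on simulated data: fragments for the real genes were drawn at these depths, with 200 genes changed by known folds and a dispersion of 0.1. The changed genes were picked from those with a mean FPKM of at least 5, so the recovery of lower genes was not tested. At a fold of 2, 0 of 50 changed genes were recovered, and at a fold of 4, 4 of 50. At a fold of 8, 13 of 50 were recovered, and at a fold of 16, 25 of 50. In the same simulation 3 unchanged genes were called, with 9195 genes in the fit. This count arose with 200 changed genes present, so it is not the number to expect where no gene changes. At 100 times the depth, the recovered numbers at folds of 2, 4, 8 and 16 were 11, 43, 50 and 50 of 50.

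Eldr itself had no values among the rows used, nor had Il6, Mmp3, Acan, Col10a1 and Gli1, so their levels were not analysed here. These rows were all typed as protein-coding and had a mean FPKM of at least 0.25. The alternatives were a pseudocount of 0.1, no filter, a mean FPKM of at least 5, median-of-ratios scaling, quantile normalization, no trend, array quality weights, the replicate number as a block, an absolute log2 fold change of at least 1, and leaving out each library in turn. Further alternatives were chosen after seeing the data: leaving out 5 rows of doubtful identity, leaving out 11 predicted genes with or without the mitochondrial genes, and leaving out control replicates 1 and 2 together. Wherever the 11 predicted genes were left out, the libraries were also rescaled to the same summed FPKM. Ranges of adjusted p and counts over the alternatives are given without the block.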

Results

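Gene expression was measured by RNA sequencing in samples labelled as chondrocytes, 3 of them control and 3 Eldr cKI, in a study of the long noncoding RNA Eldr in chondrocyte senescence. The cell type is that of the labels. Cartilage genes summed to 7.33 to 29.9 FPKM per library and cardiomyocyte genes to 2614 to 10312, so the values leave open whether these are libraries of chondrocytes. Nothing in the labels says that the samples came from separate animals or cultures, so the spread between these samples may be technical. In the main fit, the limma SEs and p-values use a spread drawn from the mean-variance trend across genes. They do not measure a gene's own spread between samples. The depth estimated from the FPKM steps was 167566, 64167 and 84349 fragments in control replicates 1, 2 and 3. It was 103363, 69111 and 239144 fragments in Eldr cKI replicates 1, 2 and 3. Genes listed above 0 numbered 8969, 5175 and 5413 in the controls and 4420, 5814 and 8390 in Eldr cKI (exact permutation test, two-sided p = 0.8, n = 3 per group). Of all values, 46.8% were listed at 0, and 1550 of 11955 rows lay above 0 in every library. Genes that every cell uses were among those at 0: Polr2a, the largest subunit of RNA polymerase II, was listed at 0 in control replicate 3 and Eldr cKI replicate 1. A value of 0 therefore means only that the gene was listed at 0, and for such genes each library's value is given. Across genes, which are not independent replicates, the Pearson correlation of log2(FPKM + 1) was 0.37 to 0.49 between controls, 0.37 to 0.58 between Eldr cKI libraries and 0.36 to 0.61 between groups.

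**Figure D1:**
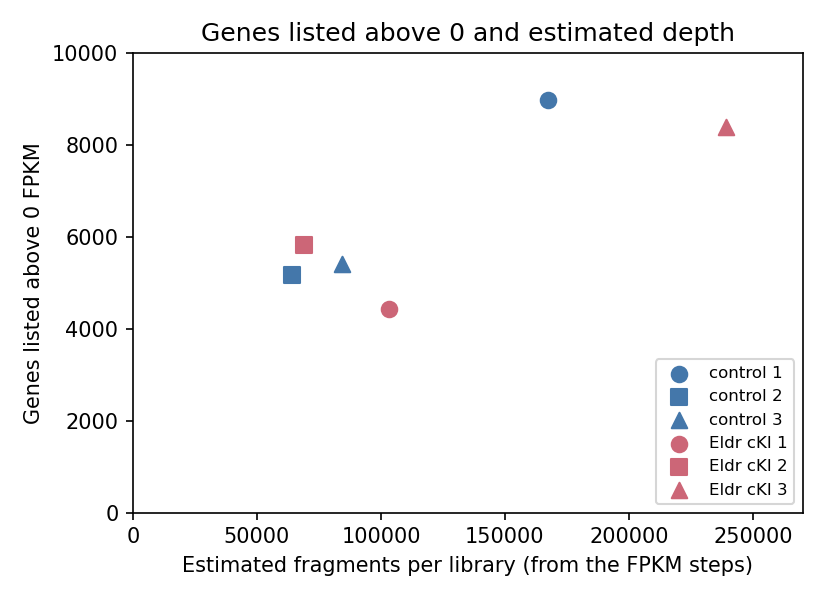
Genes listed above 0 FPKM (y axis) against the estimated number of fragments (x axis), 1 point per library, coloured by group and shaped by replicate. Control replicate 1 and Eldr cKI replicate 3, the libraries with the highest estimated depth, list 8969 and 8390 genes, and the other libraries list between 4420 and 5814.

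The comparison of Eldr cKI with control asks which genes differ when the Eldr locus is altered as the label states. In Eldr cKI, 3 of 10772 genes were lower and 0 were higher past the threshold (limma, Benjamini-Hochberg). The count was 12 without control replicate 1, 0 without control replicate 3, 0 without Eldr cKI replicate 1 and 5 without Eldr cKI replicate 2. With 11 predicted genes left out and libraries rescaled, 1 gene was higher on the log scale, mt-Atp6, and 2 were lower, mt-Nd6 and the row labelled Foxo1. With the mitochondrial genes left out as well, 2 were higher, Myh6 and Hist2h2bb, and 1 was lower, the row labelled Foxo1. The 3 genes of the comparison with all rows were the mitochondrially encoded genes mt-Nd6 and mt-Nd5, both subunits of respiratory complex I, and a row labelled Foxo1. At the level of gene lists, mitochondrially encoded genes fell, and replication-dependent histones, G2 and mitosis genes, DNA replication genes and epithelial markers rose (camera). The mitochondrial and histone lists had been fixed as lists of RNA quality, and the epithelial list as one of another cell type. None of these 5 lists passed with an estimated correlation, and with fry 0 lists passed (smallest adjusted p = 0.572). The number of lists was 1 without control replicate 3 and 1 without Eldr cKI replicate 3. Cartilage genes were low in every library, and those of the senescence list did not pass the test. At an unadjusted p under 0.05, limma gave 252 genes, 73 higher and 179 lower. In the authors' deposited table, 237 rows had a p under 0.05, of which 84 were higher and 153 lower, the smallest q was 0.134 and 0 rows had a q under 0.05.

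mt-Nd6 (ENSMUSG00000064368.1, chromosome M, 13552 to 14070, minus strand) was at 75286 ± 69531 FPKM in control and 15404 ± 11409 in Eldr cKI (SD, n = 3), and its limma log2 fold change was -2.13 (SE 0.24, adjusted p = 4.64e-15). mt-Nd5 (ENSMUSG00000064367.1, chromosome M, 11742 to 13565, plus strand) was at 15974 ± 7768 FPKM in control and 6861 ± 6134 in Eldr cKI (SD, n = 3), with a limma log2 fold change of -1.68 (SE 0.35, adjusted p = 0.00434). mt-Nd6 alone held 36.1% of all FPKM in control replicate 3 and 3.96% to 18.9% in the other libraries. Whether strand was used in counting is not given. The mt-Nd6 and mt-Nd5 genes overlap at their ends on opposite strands. Their groups overlapped too: the highest Eldr cKI library had 28555 FPKM of mt-Nd6, and the lowest control had 27852. The SEs come from the mean-variance trend across genes and do not show this spread between libraries. Of the 13 mitochondrially encoded genes measured, 12 had lower and 1, mt-Atp6, had higher mean log values in Eldr cKI, with a median log2 fold change of -1.13 (camera, adjusted p = 2.12e-20). With an estimated correlation the list's adjusted p was 0.874. Over all genes 2 of the 13 passed, and adjusted over the list alone 8 did. With the 11 predicted genes described below left out and libraries rescaled, the list's median was -0.29 and that of all genes 0.25. Without control replicate 1 mt-Atp6 was lower (limma log2 fold change -2.47). mt-Atp6 was at 0.0439, 6950 and 14442 FPKM in the controls and at 150, 5698 and 6785 in Eldr cKI, so its higher log mean rests on control replicate 1, and its mean FPKM was lower in Eldr cKI. mt-Cytb had a limma log2 fold change of -1.25 (SE 0.37) and did not pass (adjusted p = 0.451). Its log2 fold change was -0.66 without control replicate 3, -0.03 without Eldr cKI replicate 1 and -1.93 without Eldr cKI replicate 2, where it passed, and it passed in 2 of 16 alternatives. mt-Nd4, at 2636, 40.2 and 13775 FPKM in the controls and 16.7, 25.6 and 4169 in Eldr cKI, did not pass (limma, adjusted p = 0.201). Its log2 fold change of -3.19 became -1.40 without control replicate 3, -1.78 without Eldr cKI replicate 1, -2.07 without Eldr cKI replicate 2, -5.59 without control replicate 2 and -5.72 without Eldr cKI replicate 3. It passed without control replicate 2 and without Eldr cKI replicate 3, and in 5 of 16 alternatives in all.

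Mitochondrial genes held 29.1%, 50.9% and 68.3% of all FPKM in control replicates 1, 2 and 3, and 8.51%, 43.9% and 31.1% in Eldr cKI (exact permutation test, two-sided p = 0.3, n = 3 per group). In Eldr cKI replicate 1, a set of 11 predicted genes that includes Gm10800 and Gm21738 held 66.6% of all FPKM, against 4.54% to 17.4% in the other libraries. Without Eldr cKI replicate 1, the limma log2 fold change of mt-Nd6 was -1.79 (adjusted p = 0.863) and that of mt-Nd5 was -0.69 (adjusted p = 0.863), and the list's median was -0.05 (camera, adjusted p = 0.145). Control replicate 3, with the highest mitochondrial share, also held 26369 FPKM of hepatocyte genes, against 205 to 847 in the other libraries. Without control replicate 3 the log2 fold changes were -1.41 and -1.34 and neither gene passed (limma, adjusted p = 0.958 for each), the list's median was -0.77 (camera, adjusted p = 0.189), and without control replicate 2 mt-Nd5 did not pass (limma, adjusted p = 1.00). Over the alternatives the limma adjusted p ranged from 6.14e-42 to 0.999 for mt-Nd6 and from 1.41e-09 to 1.00 for mt-Nd5, and the list's from 3.24e-47 to 0.874. Both calls were also lost without the mean trend, with a filter at 5 FPKM, with quantile normalization and without control replicates 1 and 2, and that of mt-Nd5 also with array quality weights and without the 11 predicted genes. The list did not pass with quantile normalization (camera, median -0.36, adjusted p = 0.0905).

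**Figure D2:**
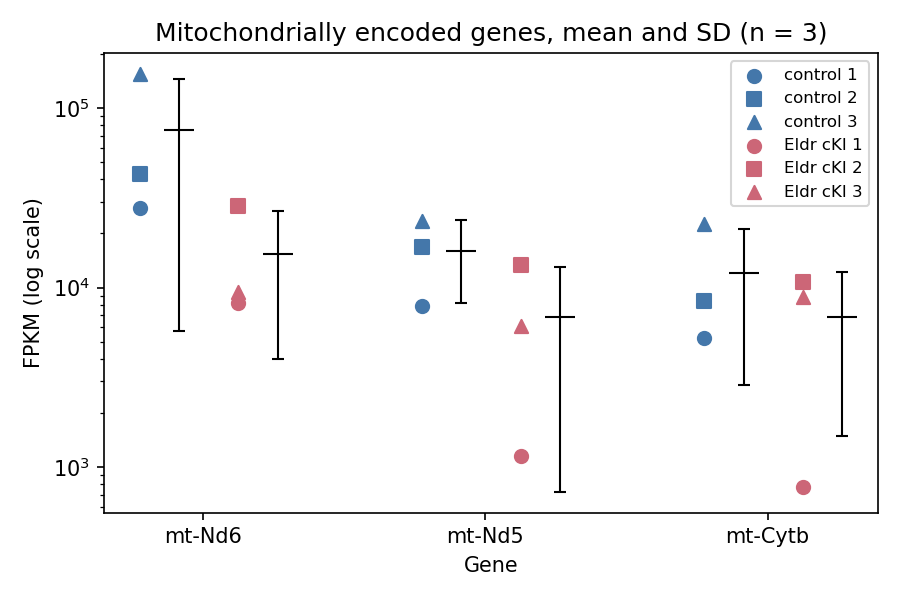
FPKM on a log scale (y axis) of mt-Nd6, mt-Nd5 and mt-Cytb, with 1 point per library coloured by group and shaped by replicate, and black bars for the group mean and SD (n = 3). Eldr cKI replicate 1 is the lowest library for each gene, and Eldr cKI replicate 2 lies above control replicate 1 for each.

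The row labelled Foxo1, a name that belongs to a forkhead transcription factor, was listed at 10.4, 119 and 3573 FPKM in control replicates 1, 2 and 3 and at 0 in all Eldr cKI libraries (limma, adjusted p = 0.000541). Its identity is uncertain. The table places it on chromosome 3 from 52175757 to 52260642 on the minus strand, whereas GENCODE M21 places Foxo1 on the plus strand from 52268336 to 52353221. Without control replicate 3 the row did not pass (limma, adjusted p = 0.662), nor without Eldr cKI replicate 1 (adjusted p = 0.757), and over the alternatives its limma adjusted p ranged from 6.14e-06 to 0.757. Mup20, a major urinary protein made in liver, was listed at 0, 31.3 and 3622 FPKM in the controls and at 0 in all Eldr cKI libraries, and did not pass (limma, adjusted p = 0.201), though it did in 3 of 17 alternatives, 1 of them without control replicate 1. Mup20 shares sequence with other genes of its family, so reads could be split among them.

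The row labelled Ihh, a name that belongs to the Indian hedgehog ligand of growth plate chondrocytes, was listed at 0 in the 3 controls and at 25.0, 12.5 and 44.7 FPKM in Eldr cKI replicates 1, 2 and 3. It did not pass (limma, adjusted p = 0.541). In the authors' deposited table its p was 0.000794 and its q 0.493. Its identity is uncertain as well: the row lies on chromosome 1 from 74984474 to 74990831 on the plus strand, outside the annotated Ihh gene at 74945315 to 74951672 on the minus strand. The Hedgehog list had 8 measured genes, 4 with higher and 4 with lower mean log values (camera, adjusted p = 0.187). It had 0 genes past the threshold over all genes and 1, the row labelled Ihh, adjusted over the list alone. Ptch1, the Hedgehog receptor, was listed at 1.984, 1.9996 and 0 FPKM in the controls and at 0.421, 0 and 0.882 in Eldr cKI.

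Replication-dependent histone genes rose as a list, with 15 of 17 measured members higher and a median log2 fold change of 1.53 (camera, adjusted p = 0.000445). With an estimated correlation the adjusted p was 0.874. Over all genes 0 of the 17 passed, and adjusted over the list alone 1 did. Hist1h4i was listed at 34.1, 0 and 0 FPKM in the controls and at 25.1, 69.1 and 293 in Eldr cKI (limma log2 fold change 4.63, SE 1.36), did not pass, and passed in 2 of 17 alternatives, 1 of them without control replicate 1. Hist1h2ab was at 59.4, 0 and 0 FPKM in the controls and at 43.5, 26.3 and 120 in Eldr cKI. Hist1h1c, a linker histone, was at 87.6, 9.92 and 7.60 FPKM in the controls and at 76.3, 71.9 and 129 in Eldr cKI, and Hist1h1b was at 46.5, 0 and 0 in the controls and at 0, 19.3 and 141 in Eldr cKI. Hist1h3b, Hist1h2ai and Hist2h2bb, which are not on the list, were among the genes with higher values that had the smallest unadjusted p, and none passed. Hist1h3b was listed at 47.6, 0 and 0 FPKM in the controls and at 142, 34.9 and 116 in Eldr cKI, and passed in 1 of 17 alternatives, without control replicate 1. Hist1h2ai was listed at 20.4, 0 and 0 FPKM in the controls and at 81.4, 18.3 and 121 in Eldr cKI. Hist2h2bb was listed at 1078, 313 and 0 FPKM in the controls and at 112, 933 and 1638 in Eldr cKI. Its limma log2 fold change of 3.00 ranged from -0.06 without control replicate 3 to 4.97 without control replicate 1, and it passed in 4 of 17 alternatives. Histone genes are near-identical copies, so reads could be split among them. Which enrichment each library had is not given, and whether library preparation moved this list was not tested. The list no longer passed without control replicate 2 (camera, median 0.70, adjusted p = 0.0536), control replicate 3 (median 0.71, adjusted p = 0.189) or Eldr cKI replicate 3 (median 0.32, adjusted p = 0.236), and without control replicate 1 the median was 2.76. Its adjusted p ranged from 7.16e-08 to 0.874 over the alternatives.

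The G2 and mitosis list rose, with 23 of 23 measured genes higher and a median log2 fold change of 0.95 (camera, adjusted p = 0.000445). Its adjusted p was 0.874 with an estimated correlation, and 0 of its genes passed over all genes or adjusted over the list alone. Cenpf, a kinetochore protein, was listed at 6.99, 0 and 0 FPKM in the controls and at 4.17, 6.88 and 32.0 in Eldr cKI. Plk1, a mitotic kinase, was listed at 0 in every library but Eldr cKI replicate 3, at 19.8 FPKM. Anln was at 10.6, 0 and 0.733 FPKM in the controls and at 11.6, 4.07 and 22.7 in Eldr cKI, and Ube2c was at 15.6, 0 and 0 in the controls and at 5.58, 5.53 and 21.2 in Eldr cKI. The DNA replication list rose, with 22 of 26 genes higher and a median of 0.75 (camera, adjusted p = 0.0200). Its adjusted p was 0.874 with an estimated correlation, and 0 of its genes passed in either count, over all genes or adjusted over the list alone. Pcna, the sliding clamp of DNA polymerase, was at 15.96, 0 and 0 FPKM in the controls and at 0, 14.5 and 68.7 in Eldr cKI. Mcm6, a helicase subunit, was listed at 0 in the controls and at 0, 11.9 and 28.9 FPKM in Eldr cKI, while Mcm4 was at 20.4, 4.34 and 0 in the controls and 2.70, 63.2 and 30.5 in Eldr cKI. Chaf1b was listed above 0 only in Eldr cKI replicate 3, at 6.41 FPKM. Summed over the G2 and mitosis list, FPKM was 192, 28.4 and 36.1 in the controls and 39.7, 124 and 516 in Eldr cKI, and over the DNA replication list it was 171, 53.7 and 21.02 in the controls and 27.6, 156 and 449 in Eldr cKI. Genes of the G2 and mitosis list above 0 numbered 19, 4 and 7 in the controls and 9, 12 and 23 in Eldr cKI, and those of the DNA replication list 22, 10 and 6 in the controls and 7, 13 and 26 in Eldr cKI. Control replicate 1 and Eldr cKI replicates 2 and 3 were also the highest in housekeeping genes, with sums of 3259, 1789 and 1896 FPKM in the controls and 1041, 2514 and 3910 in Eldr cKI. They were the highest in ribosomal protein genes too, with 4472, 2744 and 1814 FPKM in the controls and 1791, 3689 and 5396 in Eldr cKI. Without Eldr cKI replicate 3 the medians were -0.01 and -0.14 and neither list passed (camera, adjusted p = 0.363 and 0.732), and without control replicate 3 the DNA replication list did not pass either (median 0.49, adjusted p = 0.189). The DNA replication list also did not pass with array quality weights (camera, adjusted p = 0.0749), without the 11 predicted genes (0.121) or without these and the mitochondrial genes (0.0769). With a mean FPKM of at least 5, neither the G2 and mitosis list nor the DNA replication list passed (camera, adjusted p = 0.0551 and 0.0582), nor did either without control replicates 1 and 2 (0.160 for each). The medians of the G2 and mitosis list and of the DNA replication list were 1.46 and 1.26 without control replicate 1, and 1.74 and 1.22 without Eldr cKI replicate 1. Over the alternatives the adjusted p ranged from 2.74e-05 to 0.874 for the former and from 0.00198 to 0.874 for the latter.

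The epithelial and keratinocyte list rose, with 7 of 7 measured genes higher and a median log2 fold change of 1.26 (camera, adjusted p = 0.0189), 0 of them past the threshold over all genes or adjusted over the list alone. The adjusted p was 0.874 with an estimated correlation. Krt8 was listed at 99.0, 0 and 0 FPKM in the controls and at 0, 65.7 and 152 in Eldr cKI, and Krt14 at 67.5, 0 and 0 in the controls and 0, 67.0 and 40.6 in Eldr cKI. Epcam was listed at 0 in the controls and at 0, 17.6 and 7.60 FPKM in Eldr cKI, and Cldn4 was above 0 only in Eldr cKI replicate 2, at 7.97. Summed FPKM of the list was 413, 98.4 and 14.5 in the controls and 19.8, 358 and 625 in Eldr cKI, highest in the same 3 libraries as the housekeeping and ribosomal protein genes. The list did not pass without Eldr cKI replicate 2 (camera, median 0.53, adjusted p = 0.452), Eldr cKI replicate 3 (median 0.79, adjusted p = 0.224), control replicate 2 (median 1.01, adjusted p = 0.134) or control replicate 3 (median 0.62, adjusted p = 0.556). It did not pass either without the 11 predicted genes (camera, adjusted p = 0.0789), with a mean FPKM of at least 5 (0.109) or without control replicates 1 and 2 (0.221). Without Eldr cKI replicate 1 the median was 2.04, and over the alternatives the adjusted p ranged from 0.000572 to 0.874.

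Of the 28 genes on the list of cartilage matrix and chondrocyte identity, 12 had values, and their summed FPKM was 24.0, 29.9 and 7.33 in the controls and 8.59, 16.7 and 17.3 in Eldr cKI (exact permutation test, two-sided p = 0.5, n = 3 per group). Col2a1, the main collagen of cartilage, was listed at 0.956, 4.52 and 0 FPKM in the controls and at 0 in all Eldr cKI libraries. Sox9, the chondrocyte transcription factor, was at 10.002, 0 and 0 FPKM in the controls and at 2.34, 0 and 4.16 in Eldr cKI. Of the 10 genes tested, 4 were higher and 6 lower (camera, adjusted p = 0.618), and 0 passed over all genes or adjusted over the list alone. Runx2 was listed at 2.87, 0 and 0 FPKM in the controls and at 1.05, 0 and 1.76 in Eldr cKI. The hypertrophy list had 8 measured genes (camera, adjusted p = 0.983), with 1, the row labelled Ihh, past the threshold adjusted over the list alone. The list of proteases and inhibitors had 11 (adjusted p = 0.790). Adamts5, an aggrecanase, was listed at 1.98, 0 and 1.44 FPKM in the controls and at 0.379, 0 and 0 in Eldr cKI.

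Cdkn2a and Cdkn2b, cell cycle inhibitors of the senescence list, were listed above 0 only in Eldr cKI replicate 3, at 10.4 and 6.81 FPKM. The same held for the collagenase Mmp13, at 1.56 FPKM. That library had the highest estimated depth, 239144 fragments, and whether these genes were listed there for depth alone was not tested. Cdkn1a was listed at 17.2, 0 and 0 FPKM in the controls and at 0, 0 and 8.65 in Eldr cKI. Lmnb1, a nuclear lamina protein, was at 25.5, 5.26 and 0 FPKM in the controls and at 0, 9.67 and 66.4 in Eldr cKI. Of 15 senescence effectors measured, 10 were higher and 5 lower (camera, adjusted p = 0.465), and of 20 secretory factors of senescent cells 5 were higher and 15 lower (adjusted p = 0.465). Both lists had 0 genes past the threshold over all genes or adjusted over the list alone. Kat6a was at 28.2 ± 29.6 FPKM in control and 13.1 ± 10.1 in Eldr cKI (SD, n = 3), and Hnrnpl at 20.6 ± 25.1 and 25.0 ± 15.8, with limma adjusted p-values past 0.9. Egfr was listed at 0.702, 0 and 7.52 FPKM in the controls and at 0, 2.56 and 3.73 in Eldr cKI.

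Of the other lists, none passed (camera). The adjusted p was 0.0882 for erythroid markers, 2 of which passed adjusted over the list alone and 0 over all genes, 0.0980 for immediate early genes, 0.116 for glial and neuronal markers, 0.168 for neutrophil and lymphoid markers and 0.358 for glycolysis and for endothelial markers. It was 0.465 for nuclear oxidative phosphorylation genes, the unfolded protein response, TGF-beta and BMP signalling and interferon-stimulated genes. It was 0.484 for ribosomal proteins, 0.507 for NRF2 genes, p53 targets, lysosomal genes, macrophage markers and NF-kB targets, and 0.636 for skeletal muscle markers. It was 0.785 for the Wnt pathway and 0.790 for fibroblast markers and cholesterol synthesis. The test pointed up while the median was negative for the unfolded protein response (-0.13), NF-kB targets (-0.26) and proteases (-0.15), and up while the mean was negative for fibroblast markers (-0.01). Summed FPKM of osteoblast markers was 27.4, 14.2 and 25.9 in the controls and 68.3, 27.7 and 4.64 in Eldr cKI, and that of adipocyte markers was 11.1, 9.02 and 11.2 in the controls and 28.7, 3.20 and 0.932 in Eldr cKI.

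Transcripts known from other tissues moved with the libraries. Summed FPKM of 34 photoreceptor genes was 2291, 3509 and 63.6 in control replicates 1, 2 and 3 and 4.38, 17.3 and 22.0 in Eldr cKI replicates 1, 2 and 3. Summed FPKM of 38 hepatocyte genes was 26369 in control replicate 3 and 205 to 847 in the other libraries, with Alb at 3939 FPKM in control replicate 3. Summed FPKM of 25 cardiomyocyte genes was 2614, 4660 and 3482 in the controls and 3163, 10312 and 4041 in Eldr cKI (exact permutation test, two-sided p = 0.6, n = 3 per group), above the cartilage list in every library. Myh6, the heart muscle myosin, was listed at 209, 489 and 195 FPKM in the controls and at 314, 1542 and 723 in Eldr cKI. Without control replicates 1 and 2, which leaves 1 control assumed to vary like the Eldr cKI libraries, limma called 0 genes, with 910 at an unadjusted p under 0.05.

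**Figure D3:**
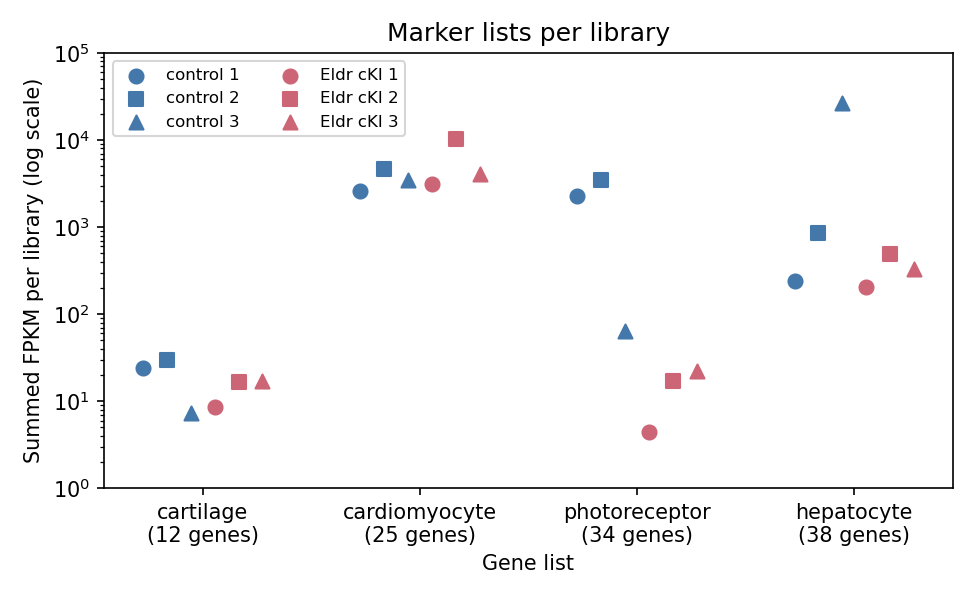
Summed FPKM per library on a log scale (y axis) for the cartilage list and for cardiomyocyte, photoreceptor and hepatocyte genes (x axis, with the number of genes that have values), 1 point per library, coloured by group and shaped by replicate. Photoreceptor genes sum to 2291 and 3509 FPKM in control replicates 1 and 2, and hepatocyte genes to 26369 in control replicate 3.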

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

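The alternatives with rows or libraries removed together were chosen after seeing the data, and the others before. The count of 3 genes became 8 with a pseudocount of 0.1, 1 with a mean FPKM of at least 5, 6 with median-of-ratios scaling, 1 with quantile normalization, 17 with array quality weights (4 higher, 13 lower) and 0 with both photoreceptor-bearing controls left out. It was 0 by limma without a trend, with 356 genes at an unadjusted p under 0.05. Leaving out each library in turn gave 0 to 12 genes: 12 without control replicate 1, 0 without control replicate 3, 0 without Eldr cKI replicate 1 and 5 without Eldr cKI replicate 2. Without the 5 rows of doubtful identity 2 genes passed, both mitochondrial, and with no filter or a log2 minimum of 1 the count was 3. The count of 5 lists became 2 with a mean FPKM of at least 5, 0 with camera and an estimated correlation, 0 with fry (1 list at an unadjusted p under 0.05) and 2 with both photoreceptor-bearing controls left out. It ranged from 1 to 7 over the libraries left out in turn, with 1 without control replicate 3 and 1 without Eldr cKI replicate 3. Without the 11 predicted genes and with libraries rescaled, the median log2 fold change of all genes was 0.25, against -0.04 in the main fit. The cause of these changes was not tested.

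With the replicate number as a block, 5 genes and 5 lists passed. Same-numbered libraries did not deviate together: the correlations of their deviations from the group means were -0.17, 0.03 and -0.15, and 1 of 6 libraries correlated best with its own number, so the block is left out of the ranges and counts over alternatives. The level of Eldr gave no value under any alternative, as Eldr had no values among the rows used. In simulated data at the estimated depth, 4 of 50 genes changed by a fold of 4 were recovered. The simulated values held 58.2% at 0, against 46.8% of the real ones. Apart from the changed genes, the simulated libraries also shared 1 mean profile, unlike the real ones. The simulation therefore does not settle which changes were detectable in the real data.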

Other observations

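All tests in this part were chosen after the results were seen. For the 11 predicted genes, what the test would show was written before its own value was seen. Receptor genes of the olfactory and vomeronasal families, which are not expected in cartilage, were listed as well. The 279 such genes summed to 257, 141 and 433 FPKM in control replicates 1, 2 and 3 and to 773, 188 and 69.9 in Eldr cKI replicates 1, 2 and 3. Adult globins were low in 1 library: Hbb-bs was listed at 46.9 FPKM in Eldr cKI replicate 3 and at 85.6 to 320 in the others, and Hba-a1 at 0 there and at 88.9 to 224 in the others. Of 25 housekeeping genes, 18 lay above 0 in every library. Poisson sampling at the estimated depths, given each row's mean FPKM, would give 41114 values of 0 over the 11939 rows whose gene is in GENCODE M21, and 33483 were listed there. In Eldr cKI replicate 1 the order was the other way, with 7525 listed over the same rows and 6990 from sampling.

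Photoreceptor genes were high in control replicates 1 and 2 only. Of the 34 with values, 32 (94.1%) lay above 0 in both, among them Gnat1 at 268 and 351 FPKM. This share does not decide whether RNA or reads from retina were present, because the list was written after the values were seen and its genes have values only where their mean FPKM reached 0.25. A genotype difference stays open, since only 1 library bears on it: control replicate 3 reached 2.19% of the mean of the other controls. In control replicate 3, 100% of the 38 hepatocyte genes with values lay above 0, with Alb at 3939 and Mup20 at 3622 FPKM. For the same reasons this share leaves RNA or reads from liver open. For the hepatocyte genes, the higher of the other controls reached 3.21% of control replicate 3, so the high level was not shared by the controls. As the list was written after the values were seen, this does not decide on a genotype difference. Where such RNA or reads would have entered, in dissection, library preparation or sequencing, was not tested, and 0 of the genes on either list are on a list fixed beforehand.

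The rows named Hpip, Errγ, Ihh, Itgbl1 and Foxo1 differ in form from the other 11950 rows, and their identities are uncertain. All 5 break the table's order of gene identifiers and have the length of the annotated gene at a shifted position, which 0 other rows do. The identifiers of the rows named Hpip and Errγ also stand on the rows of Hcfc1r1 and Esrrg, with other values. Of the other rows, 0.0% lie wholly outside the span of their own gene, and among these 5 rows 3 do. This argues against shifted coordinates for the whole table. It cannot decide on another annotation release for the whole table, which could change spans without moving genes outside them. Of all 11955 rows, 11017 have exactly the GENCODE M21 span. Whether these 5 rows alone carry the coordinates of another release was not tested and stays open. The 5 rows are also unlikely to be irregular at random with respect to the comparison: all 5 have a p under 0.05 in the authors' deposited table, against 232 of the other rows (Fisher's exact test, two-sided p = 2.94e-09), and how they came to differ stays open.

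The fall of mt-Nd6 and mt-Nd5 could come in part from the 11 predicted genes that held 66.6% of FPKM in Eldr cKI replicate 1, since FPKM is scaled to each library's mapped fragments. Without those rows and with libraries rescaled to 1 total, the median log2 fold change of both genes was -1.07, between the bounds set for and against this explanation. The rescaling also evened out summed FPKM, which ran from 188859 in Eldr cKI replicate 1 to 430062 in control replicate 3. Leaving out the rows and rescaling were not tested apart, so the change cannot be laid to the 11 genes alone. mt-Nd6 went from -2.13 (SE 0.24) to -1.30 (SE 0.18) and passed in limma (adjusted p = 2.43e-09). As these SEs come from the trend across genes, this does not decide whether the 11 genes are its whole cause. mt-Nd5 went from -1.68 (SE 0.35) to -0.85 (SE 0.27) and did not pass, because its fold shrank by more than its error (adjusted p = 0.635). Over their alternatives the adjusted p ranged from 6.14e-42 to 0.999 for mt-Nd6 and from 1.41e-09 to 1.00 for mt-Nd5, and a genotype difference stays open, untested apart from the comparison itself.

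The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. As many genes as the real 3 were called by 6 of the 10 splits, the real one included, and the highest of the others was 10. For lists, the real value was 5, 5 of the 10 splits gave as many, and the highest other was 12. The split of control replicate 1 with Eldr cKI replicates 2 and 3 against the rest gave the 12 lists. At an unadjusted p under 0.05 it gave 1429 genes, against 252 in the real one, and both counts were the highest. These 3 libraries list the most genes above 0 (8969, 5814 and 8390). In this split, 582 genes lay above 0 in these 3 libraries and at 0 in the rest, against 16 the other way. The split thus follows how many genes each library lists, and its cause was not tested.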
